A study of Mus musculus with 6 samples.

How the data were processed

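RNA sequencing values were available for 6 libraries from mouse osteoblasts, the bone-forming cells, taken from 2 skeletal sites: 3 libraries from the mandible, the lower jaw bone, and 3 from the tibia, the shin bone. Per the labels' protocols, the mice were at postnatal day 9 and carried a transgene in which a fragment of the Col1a1 promoter drives green fluorescent protein in osteoblasts. Bones were digested with collagenase and the fluorescent cells were sorted by flow cytometry. Each of 3 independent dissections pooled about 50 mice. Between 2 and 8 ng of RNA per preparation entered a low-input cDNA kit (SMART-Seq v4), followed by TruSeq library preparation and sequencing on an Illumina HiSeq instrument. The low input means that amplification precedes sequencing, so that counting error is not the whole technical error.

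The deposited values are RPKM, reads scaled by transcript length in kilobases and by the number of mapped reads, which the authors gave for each RefSeq transcript. CASAVA 1.8.2, TopHat2 2.1.0, Partek 6.6 and the mouse build mm10 are named in the submitters' processing notes, while per the file headers the RPKM calculation used Partek 6.15.1207 on mm10. Which of the versions of Partek made the values is not given in the sources used here, nor is the strand setting of the counting. RPKM corrects for transcript length and the number of mapped reads, and it makes no correction for a few transcripts taking a large share of the reads. The table held 30198 transcripts of 19679 gene symbols. A second deposited RPKM table held 2166 transcripts of transcription factors, all 2166 with values identical to those in the full table, so only the full table was used. The authors' list of 1388 mouse transcription factors, compiled from TcoF-DB v2, TFcheckpoint and UniProt per the file headers, was used to define transcription factors. Of its symbols, 1272 were in the table and 116 were not.

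Read totals were recovered from the steps of the RPKM values of genes with a single transcript, of which there were 14090. Totals (M reads) came to 49.5, 58.1 and 51.8 for mandible libraries 1, 2 and 3, and to 49.2, 52.0 and 51.8 for tibia libraries 1, 2 and 3. At these totals between 66.1% and 70.0% of the low values of these genes lay within 0.05 of a whole number of reads. For a total set beforehand, 10% would do so by chance. Each total was chosen from the same values, as the one that put the most of them at 1 read, so 10% understates the chance share here. An RPKM of 1 on a transcript of 2 kb then stands for 98 to 116 reads, depending on the library. Because values of genes with several transcripts come from estimated shares, no count model was fitted.

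Transcript values were summed per gene symbol, a choice made after the data were seen. Genes with a mean RPKM of at least 0.5 over the 6 libraries were kept, which left 12752 genes and 850 transcription factors. Differences between sites were tested on log2(RPKM + 0.5) with limma 3.58.1 in R 4.3.3, using lmFit and eBayes with a mean-variance trend, two-sided, and Benjamini-Hochberg adjustment over all genes tested at a threshold of 0.05. A fold change is therefore on the log2(RPKM + 0.5) scale, which understates the change of genes with low values. The model held the site only. Every adjusted p given for a gene comes from this limma fit unless the block is named. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.

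The libraries of both sites carry the same dissection numbers, and the labels' experiment names tie same-numbered libraries together. The deviations of the libraries from their site means correlated at 0.59, 0.66 and 0.80 across genes for the pairs numbered 1, 2 and 3. Mandible library 1 with tibia library 2 and mandible library 2 with tibia library 1 correlated nearly as much, at 0.55 and 0.52, while pairs of a library of dissection 3 with one of another number lay between -0.71 and -0.64. The correlations thus set dissection 3 apart and hardly tie the numbers 1 and 2. The numbers were taken to pair the samples from the labels and because each same-numbered pair correlated above 0.1, and the dissection number as a block was a second fit, fixed before the data were examined along with the model without it and the gene lists. Preparations were pools of many mice, so the p-values measure the spread between 3 pooled preparations, not between mice.

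Of 31 gene lists with 610 entries, 30 had at least 3 tested genes and were tested with camera, which compares the genes of a list with all other genes, at a preset correlation between genes of 0.01. Benjamini-Hochberg adjustment was over the 30 lists. Alternatives were an estimated correlation, the directional test of fry, and both kinds of fit. None of the genes of the list of mitochondrially encoded transcripts were in the table, so it was not tested. In all, 28 list entries were not in the table, and 2 genes were found under older symbols (Cnmd as Lect1, Snorc as 3110079O15Rik). Genes named in the text followed a rule fixed before the data were examined. It took the 10 genes with the largest fold change in each direction among those that passed and whose 3 values in one site all lay above the 3 of the other, and the same among transcription factors. Where fewer than 10 transcription factors passed in a direction, the next by p were added, up to 5, and are given as not passed. It also took up to 4 passed members of every list by fold change and its 2 members with the highest mean RPKM, and some osteoblast genes, among them Col1a1, Runx2, Sp7 and Dlx5, whatever their values. The rule gave 99 genes, and the values of some of them are not reported here. Any other gene is named as a member of a list or of a count, and was chosen after its values were seen.

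Detection was counted separately as an RPKM of at least 1 in all 3 libraries of a site. Gene coordinates are 1-based positions on GRCm38, the assembly mm10 stands for, from the GENCODE M21 annotation. Transcript lengths from the same annotation were found for 12625 of the 12752 genes (99.0%). The tests were tried on simulated data built from the means and spread of these libraries, in which 68, 66 and 66 of 12752 genes were changed by 1, 2 and 3 on the log2 scale. Without the block, these were recovered for 4.4%, 60.6% and 87.9% of the genes, and with the block in 35.3%, 84.8% and 87.9%. Each simulated dissection had the same deviation at both sites, so the pairing, and with it the gain from the block, was built in. There were 0 false calls among 12552 unchanged genes in either fit. A simulated list of 20 genes shifted by 1 gave a camera p of 1.69e-52, and 2 of 100 unshifted lists had an unadjusted p under 0.05. These lists were random genes with noise drawn separately for each gene. They cannot show how often camera makes false calls on lists of genes that vary together.

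Alternatives fixed beforehand were pseudocounts of 0.1 and 1, no filter or a filter at a mean RPKM of 2, quantile normalization, median-of-ratios scaling, library weights, robust variance estimation, the block, a fold change of at least 2, other detection rules, and leaving out each library or each dissection. Added after the data were seen were the transcript with the highest mean in place of the sum, leaving out both libraries of dissection 3, removing the trend with transcript length in each library (lowess, span 0.3), and the block combined with that removal or with quantile normalization.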

Results

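Osteoblasts sorted from the mandible and the tibia of mice at postnatal day 9 were compared by RNA sequencing, with 3 libraries per site from 3 dissections. The series asks which transcription factors mark osteoblasts of the jaw against those of a limb bone. Read totals, recovered from the steps of low values, were 49.5, 58.1 and 51.8 M in mandible libraries 1, 2 and 3 and 49.2, 52.0 and 51.8 M in tibia libraries 1, 2 and 3, and between 10765 and 11249 genes had an RPKM of at least 1. Values below are mean RPKM ± SD over the 3 libraries of a site (n = 3), and log2 fold changes are mandible minus tibia with their standard error (SE). Over all 12752 genes tested the median log2 fold change was 0.12, against -0.01 after quantile normalization, so a gene at 0.12 moved with the bulk of the genes.

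The leading principal component held 60.9% of the variance and set both libraries of dissection 3, at 42.3 and 66.6, apart from the 4 others. The second component held 24.5% and parted the sites, with mandible libraries at 18.7, 21.3 and 33.3 and tibia libraries at -30.9, -28.2 and -14.2. Haemoglobin transcripts made up 0.72%, 2.42% and 4.51% of all RPKM in mandible libraries 1, 2 and 3, and 1.87%, 4.57% and 9.78% in tibia libraries 1, 2 and 3.

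**Figure D1:**
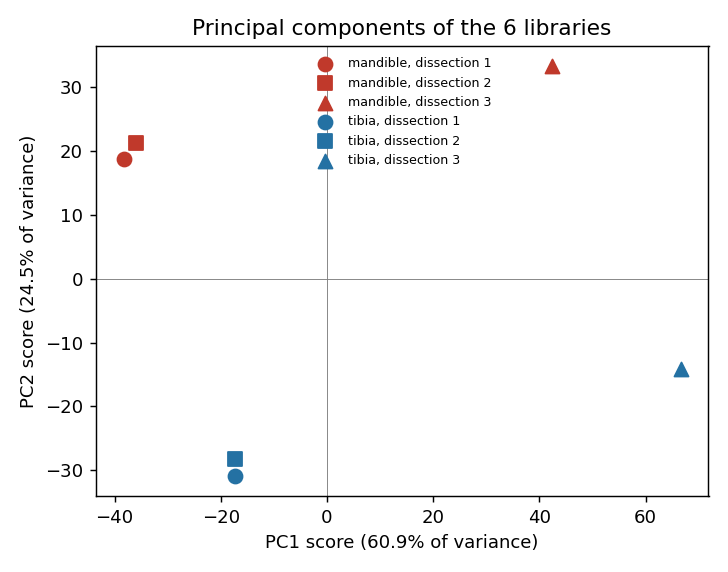
Scores of the 6 libraries on the leading principal components of log2(RPKM + 0.5), 1 point per library, with the percent of variance on each axis, colour by site and marker shape by dissection. Both libraries of dissection 3 lie at 42.3 and 66.6 on the horizontal axis, and the sites part on the vertical axis.

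Transcription factors that pattern the face were higher in the cells sorted from the mandible, and Hox factors, which set position along the trunk and limbs, were higher in those sorted from the tibia. Of 850 transcription factors tested, 25 passed, 17 of them higher and 8 lower in the mandible, and 36 passed when adjusted over the list alone. The LIM homeobox factor Lhx8 was at 9.01 ± 3.83 RPKM in the mandible and 0.0572 ± 0.0485 in the tibia, a log2 fold change of 4.0 (SE 0.34, adjusted p = 0.00410). Hoxc10 was at 0.0363 ± 0.0544 in the mandible and 12.2 ± 0.999 in the tibia, a log2 fold change of -4.57 (SE 0.17, adjusted p = 0.000255). In the same mandible libraries, marker lists of other cell types were also on the higher side, with medians of 3.11 for ameloblast, 0.98 for odontoblast and dental mesenchyme, 1.08 for cartilage, 1.12 for Schwann cell and 1.41 for epithelial genes. With an estimated correlation the ameloblast list kept its call (adjusted p = 0.0325) and the others, in the same order, did not (adjusted p = 0.0691, 0.367, 0.111 and 0.0691).

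Jaw and facial patterning factors formed the largest group. The list of these factors had a median log2 fold change of 1.60, and 10 of its 17 tested members rose (14 adjusted over the list alone; camera adjusted p = 1.01e-25, and 0.00523 with an estimated correlation). Alx1, a homeobox factor of the facial skeleton, was at 10.6 ± 3.01 RPKM in the mandible against 0.360 ± 0.122 in the tibia, a log2 fold change of 3.67 (SE 0.24, adjusted p = 0.00240). Hand2, a basic helix-loop-helix factor of the ventral jaw arch, differed by 3.27 (SE 0.28), from 0.189 ± 0.0986 in the tibia to 6.34 ± 2.32 in the mandible. Pax3, a neural crest factor, rose by 2.80 (SE 0.19), the forkhead factor Foxf1 by 2.49 (SE 0.29) and Barx1 by 1.85. Further called members included Tfap2b (1.60), Six2 (1.56) and Gsc (1.25), and outside the lists the zinc finger factor Glis1 rose by 1.55. Lhx8 and Barx1 are also in the list of odontoblast and dental mesenchyme genes (median 0.98). In GRCm38 Lhx8 lies at chromosome 3, 154306294 to 154330659, Alx1 at chromosome 10, 102998707 to 103030215 and Hand2 at chromosome 8, 57320983 to 57324633.

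Distal-less and Msx homeobox factors, which act in jaw and tooth patterning, rose in the mandible for 4 of 8 tested genes (6 adjusted over the list alone), and all 8 had a log2 fold change above 0. The median was 1.96 (camera adjusted p = 1.29e-11, and 0.0187 with an estimated correlation). Dlx4 at chromosome 11, 95140447 to 95146263 was at 18.3 ± 0.233 RPKM in the mandible and 1.38 ± 0.406 in the tibia (3.34, SE 0.20, adjusted p = 0.00173). Msx1 rose by 2.64 (SE 0.29, adjusted p = 0.0124), Msx2 by 2.22 (SE 0.25, adjusted p = 0.0127) and Dlx2 by 1.77. Dlx5, the most abundant of the group at 65.3 ± 7.38 and 51.9 ± 8.10 RPKM, did not pass (0.33, adjusted p = 0.785). Dlx3 stood at 1.17 without passing (adjusted p = 0.150; 0.00323 with the dissection as a block), and is also in the ameloblast list (median 3.11).

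All 8 Hox genes above the filter were lower in the mandible, and 7 of them passed (8 adjusted over the list alone; median -2.26, camera adjusted p = 1.39e-32, and 0.00523 with an estimated correlation). In the mandible these genes were near the floor, with the highest mean at 0.242 RPKM (Hoxd8). Of 34 Hox genes in the table only these 8 were above the filter, a mean of 0.5 over the 6 libraries. They could reach it only through their tibia values, so the direction shared by all 8 follows from the filter. Hoxa10 was at 0.0121 ± 0.0136 RPKM there and 9.89 ± 0.252 in the tibia (-4.34, SE 0.15, adjusted p = 0.000255). Hoxa7 fell by 2.79 and Hoxa9 fell by 2.66 on the log2 scale, with tibia values of 3.76 ± 0.522 and 3.03 ± 0.513. Hoxd8 (-1.85), Hoxc9 (-1.72) and Hoxa5 (-1.58) also fell. Hoxa5, Hoxa7, Hoxa9 and Hoxa10 lie in the Hoxa cluster on chromosome 6, at 52201754 to 52204587, 52214491 to 52221854, 52223100 to 52231089 and 52231197 to 52240854. Hoxc10 and Hoxc9 lie on chromosome 15, at 102966796 to 102971893 and 102976439 to 102985099. Neighbouring Hox transcripts overlap, so reads may be shared between members of a cluster. Hoxc5 was listed at 0 in the 3 mandible libraries and at 1.28, 0.423 and 1.44 RPKM in tibia libraries 1, 2 and 3, and did not pass (adjusted p = 0.0998; 0.0208 with the block and 0.0317 without tibia library 2).

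Factors of limb patterning went both ways. Tbx18 fell in the mandible (-1.34, SE 0.16, adjusted p = 0.0158), while Hand2, already named, and the zinc finger factor Sall3 (1.79, adjusted p = 0.0494) rose. Tbx4, a factor of the hindlimb, was at 0.252 ± 0.169 and 1.27 ± 0.286 RPKM without passing (-1.25, adjusted p = 0.0977; 0.0188 with the block). Prrx1 at -0.41 and Shox2 at -0.86 (adjusted p = 0.222; 0.0185 with the block), the most abundant members, did not pass. Of 14 members, 2 rose and 1 fell (6 and 4 adjusted over the list alone; 5 and 4 with the block). The list median was -0.02 and its mean 0.31, and camera, which put it on the lower side, did not pass (adjusted p = 0.531; 0.0271 without mandible library 1). Other homeobox factors had 6 of 38 members higher (9 higher and 1 lower adjusted over the list alone; 10 higher and 1 lower with the block; median 0.36, camera adjusted p = 0.000279), a call lost at adjusted p = 0.0895 with an estimated correlation. Their most abundant members, Tgif1 at -0.04 and Cux1 at 0.54, did not pass. Over the 3 homeobox lists, 17 of 54 transcription factors passed (31.5%), against 8 of 796 factors outside these lists (1.0%; Fisher's exact test, two-sided, odds ratio 44.6, p = 2.39e-16). The split is by list, and Pax3, in the jaw list only, was counted outside. The comparison was chosen after the calls were seen, so its p-value is no separate evidence. It was made across genes, which are not independent.

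**Figure D2:**
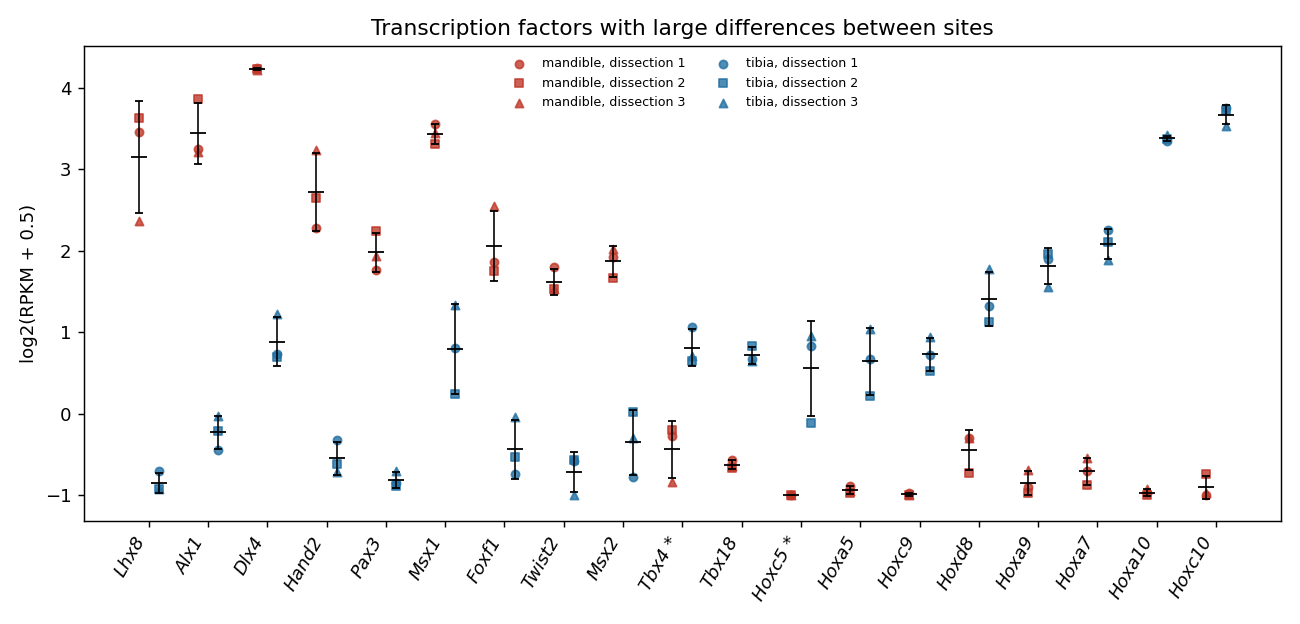
Log2(RPKM + 0.5) of transcription factors named by the rule, in each library (points, marker shape by dissection), with mean and SD over 3 libraries per site (black). Factors to the left are higher in the mandible and those to the right higher in the tibia, and Tbx4 and Hoxc5, marked by an asterisk, did not pass.

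With the dissection as a block, 73 transcription factors passed, 50 higher and 23 lower, the 25 above among them. Without both libraries of dissection 3, chosen after seeing the data, 78 passed, 61 higher and 17 lower, with 24 of the 25 kept. Without mandible library 1, 2 or 3 the fit called 13, 13 and 30 factors, and without tibia library 1, 2 or 3 it called 13, 18 and 20.

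Most regulators that define the osteoblast did not pass. Runx2 was at 14.4 ± 0.633 RPKM in the mandible and 13.7 ± 0.398 in the tibia (0.08, SE 0.16, adjusted p = 0.966; -0.05 after quantile normalization). Sp7, also called osterix, was at 34.9 ± 16.6 and 31.0 ± 15.5 (0.19, SE 0.57, adjusted p = 0.976). Of 30 osteoblast factors, 2 rose, namely Twist2 (2.34, SE 0.20, adjusted p = 0.00387) and Msx2, and 3 were higher adjusted over the list alone. The list did not pass (median 0.18, camera adjusted p = 0.389), and its most abundant members, Atf4 (0.24) and Creb3l1 (-0.29), did not pass either. Among 25 genes of bone matrix and its mineralization none passed, also when adjusted over the list alone. Their median was 0.05 (-0.08 after quantile normalization) and their mean 0.06, while camera put the list on the lower side without passing (adjusted p = 0.486). Col1a1, the main collagen of bone, was at 13300 ± 6703 and 19550 ± 10050 RPKM (-0.55, SE 0.74, adjusted p = 0.952; 0.0310 with the block). It was at 0.00 without mandible library 3, and at -0.24, -0.29 and -1.10 without tibia library 1, 2 or 3, but at -0.52, -0.56 and -0.56 without both libraries of dissection 1, 2 or 3, and was lower in the mandible in each dissection. Osteocalcin, Bglap, was at 21570 ± 5742 and 22610 ± 14320 (0.08, adjusted p = 0.990; -0.06 with median-of-ratios scaling), and shares reads with its near-identical copies. With the block 2 matrix genes were higher and 2 lower. Osteocyte genes had a median of 0.34, with none of 12 passing, also adjusted over the list alone (camera adjusted p = 0.0975; 0.0460 without mandible library 2), and the median was 0.13 without mandible library 3. With the block 2 were higher and the list had an adjusted p = 0.00687, and adjusted p = 0.284 with an estimated correlation as well. Dmp1 stood at 0.45 and Mepe at 0.76 (adjusted p = 0.905; 0.0187 with the block). Over left-out libraries Dmp1 ranged from 0.12 to 0.73, and Mepe was at 1.16 and 0.14 without mandible library 2 or 3 and at 0.25 and 1.36 without tibia library 2 or 3. Without both libraries of dissection 1, 2 or 3 Mepe was at 0.89, 0.65 and 0.74. Without the block the SE of Col1a1 and Sp7 was 0.74 and 0.57, so those p-values do not show that the genes are alike at both sites. With the block the SE was 0.10 for each, and Sp7 still did not pass (adjusted p = 0.286).

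Detection separated some of the same factors. With detection set at an RPKM of at least 1 in all 3 libraries, 641 factors were detected in the mandible, 599 in the tibia and 575 in both. A further count took factors detected at one site only, and 22 were detected in every mandible library and in no tibia library, among them Alx1, Alx4, Barx1, Batf3, Dlx2, Foxf1, Gsc, Hand2, Lhx8, Msx2, Pax3, Pax9, Six2, Twist2, Zfp14, Zfp286, Zfp438, Zfp60, Zfp74, Zfp839 and Zscan18. The reverse held for 7, namely Hoxa10, Hoxa7, Hoxa9, Hoxc10, Hoxd8, Tbx18 and Tbx4. No test stands behind this count. Some of the 22 lie close to the limit on both sides, such as Zfp839 at 1.20 and 0.967 RPKM. Counting by the group mean gave 73 and 26, leaving out mandible library 3 gave 43 and 12, and leaving out both libraries of dissection 3 gave 47 and 15.

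Genes of enamel and dentine had the largest fold changes among all genes that passed. Amelx, which encodes the enamel protein amelogenin, was at 1005 ± 694 RPKM in the mandible and 2.29 ± 0.20 in the tibia (8.19, SE 0.57, adjusted p = 0.00269). Ambn, encoding ameloblastin, was at 306 ± 144 against 4.07 ± 0.285 (5.96, SE 0.34, adjusted p = 0.00154), and Dspp, a dentine matrix gene of odontoblasts, at 44.1 ± 31.2 against 0.155 ± 0.0717 (5.68, SE 0.69, adjusted p = 0.0187). In all, 124 of 12752 genes passed, 111 higher and 13 lower in the mandible, and 1147 had an unadjusted p under 0.05.

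Other leading genes higher in the mandible were Rspo4, an activator of Wnt signalling (5.34, SE 0.48, adjusted p = 0.00491), the matrix gene Coch (4.44, SE 0.36), the hormone gene Sct, encoding secretin (3.86, SE 0.32), and the uncharacterised locus LOC102636514 (4.25). Lower in the mandible, besides Hox genes, were the transcripts Hoxa11os (-3.33, SE 0.17, adjusted p = 0.00129) and Mira (-2.07, SE 0.27) of the Hoxa cluster and the cytochrome P450 gene Cyp4b1 (-1.48, SE 0.18, adjusted p = 0.0177). Without knowledge of strand, reads of Hoxa11os and Mira cannot be told from those of overlapping genes on the other strand. With the dissection as a block 828 genes passed, 566 higher and 262 lower, all 124 among them. The share of calls higher in the mandible was 89.5% without the block and 68.4% with it, and 45.9% when the block was combined with quantile normalization. Leaving out mandible library 1, 2 or 3 gave 46, 40 and 141 calls, leaving out tibia library 1, 2 or 3 gave 37, 48 and 72, and leaving out both libraries of dissection 3 gave 724 (557 higher and 167 lower).

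Gene lists for other cell types of the jaw were higher in the mandible. Of 7 ameloblast genes, which make enamel, 4 rose (6 adjusted over the list alone; median 3.11, camera adjusted p = 5.85e-10, and 0.0325 with an estimated correlation). They were Amelx, Ambn, Mmp20 (3.43, SE 0.40) and Enam (3.12, SE 0.36), while Klk4 did not pass (-0.61). Among odontoblast and dental mesenchyme genes 3 of 10 rose, Dspp, Lhx8 and Barx1 (7 adjusted over the list alone; 6 with the block; median 0.98, camera adjusted p = 4.59e-07), and the call was lost at adjusted p = 0.0691 with an estimated correlation. Igfbp3, an abundant member, stood at -0.55 without passing.

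Cartilage genes had 4 of 18 members higher (10 higher and 1 lower adjusted over the list alone; 10 higher with the block; median 1.08, camera adjusted p = 2.60e-05), with the list at adjusted p = 0.367 with an estimated correlation. Col2a1, the main cartilage collagen, was at 86.2 ± 32.5 RPKM against 12.6 ± 5.14 (2.73, SE 0.37, adjusted p = 0.0256). Col9a2 (3.20, SE 0.23), Col9a3 (2.80, SE 0.38) and Lect1 (2.96, SE 0.38) also rose, whereas Col11a2 (-0.33), Acan (0.09) and Col10a1 (-1.40) did not pass. Of epithelial genes 2 of 8 rose, the keratins Krt14 (3.01, SE 0.46) and Krt8 (2.34, SE 0.35), and 6 adjusted over the list alone (4 with the block). Their median was 1.41 (camera adjusted p = 2.22e-06; adjusted p = 0.0691 with an estimated correlation), and Sfn stood at 0.35. Schwann cell and neural genes had 2 of 7 higher, among them the myelin gene Mbp (3.34, SE 0.46, adjusted p = 0.0268), and 3 adjusted over the list alone. Their median was 1.12 (camera adjusted p = 0.000731; adjusted p = 0.111 with an estimated correlation). Tubb3 stood at 1.12 (adjusted p = 0.197; 0.00450 with the block).

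Blood, marrow and vessel genes lay on the lower side in the mandible, and none of their members passed the test over all genes. Erythroid and megakaryocyte genes had a median of -1.06, with 13 of 14 below 0 (camera adjusted p = 4.82e-07; adjusted p = 0.330 with an estimated correlation), and 10 were lower with the block. That median was -0.34 and -1.78 without mandible library 1 or 3, and -1.73 and -0.40 without tibia library 1 or 3. The globin genes Hba-a1 and Hba-a2, which share reads, stood at -1.06 and -1.07 (adjusted p = 0.904 and 0.911; 0.00959 and 0.00785 with the block). Hba-a1 was at -0.23 and -1.81 without mandible library 1 or 3 and at -1.73 and -0.33 without tibia library 1 or 3, and Hba-a2 at -0.20, -1.87, -1.78 and -0.29. Myeloid genes had a median of -0.51 (camera adjusted p = 2.71e-05; adjusted p = 0.429 with an estimated correlation; 7 of 19 lower with the block), with S100a8 at -0.42 and Ngp at -0.52 (adjusted p = 0.969; 0.0466 with the block). The myeloid median was -0.08, -0.20 and -1.11 without mandible library 1, 2 or 3, and -0.77 and 0.16 without tibia library 1 or 3, with camera on the lower side throughout, and Ngp ranged from -1.62 to 0.45, lowest without mandible library 3 and highest without tibia library 3. Lymphoid genes had a median of -1.02 (camera adjusted p = 7.67e-05; 0.0774 without tibia library 3; adjusted p = 0.367 with an estimated correlation; 4 of 8 lower with the block), with Cd74 at -0.40 and Cd79b at -1.19 (adjusted p = 0.873; 0.00440 with the block). The lymphoid median was -0.52 and -1.85 without mandible library 1 or 3 and -0.40 without tibia library 3, and Cd79b was at -0.50, -2.06 and -0.43 there and at -1.82 without tibia library 1. Without both libraries of dissection 1, 2 or 3 the erythroid median was -0.91, -1.19 and -1.08, the myeloid -0.42, -0.45 and -0.62 and the lymphoid -0.73, -1.05 and -1.30. In dissection 3 the erythroid, myeloid and lymphoid medians were 1.86, 1.88 and 2.50 above the other dissections in the mandible, and 1.97, 1.28 and 2.04 above in the tibia. None of these 3 lists had a member past the threshold when adjusted over the list alone.

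Endothelial genes were below 0 for all 14 members, with a median of -0.97 (camera adjusted p = 1.12e-15; adjusted p = 0.0691 with an estimated correlation). Adjusted over the list alone 4 were lower, and 5 with the block. The most abundant, Egfl7 and Esam, stood at -0.86 and -1.05, and at -0.41 and -0.60 without both libraries of dissection 1. Marrow stromal and adipocyte genes had a median of -0.70 (camera adjusted p = 1.84e-06; adjusted p = 0.0691 with an estimated correlation), with 0 members passing adjusted over the list alone and 3 of 10 lower with the block. That median was -0.45 without both libraries of dissection 1. The chemokine gene Cxcl12 stood at -0.79 and Fabp4 at -1.06. Over left-out libraries Cxcl12 ranged from -1.60 to -0.20, lowest without tibia library 3 and highest without tibia library 1, and Fabp4 from -1.53 to -0.64, lowest without both libraries of dissection 2 and highest without mandible library 1. Mural cell genes (median 0.14, mean 0.03, camera on the lower side, adjusted p = 0.389; 0.00969 without mandible library 2), skeletal muscle genes (0.26, 0.23, lower side, adjusted p = 0.961) and osteoclast genes (0.33, adjusted p = 0.185) did not pass, nor did tendon and periosteum genes (0.60, adjusted p = 0.949). None of their members passed, also adjusted over the list alone, and with the block 3 of the tendon and periosteum genes were higher. Their most abundant members stood at -0.80 (Rgs5), 0.72 (Acta2), 0.62 (Tnnc2), 0.54 (Acta1), 0.19 (Ctsk), 0.33 (Acp5), 0.66 (Fmod) and 0.97 (Postn, adjusted p = 0.505; 0.0437 with the block; 0.65 without both libraries of dissection 1). Without both libraries of dissection 3 Rgs5 was at -0.19 and Acta2 at 1.36, and without those of dissection 1 Acta2 was at 0.38.

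Among signalling genes, 2 lists had members that passed: Wnt genes, and a joint list of bone morphogenetic protein (BMP) and transforming growth factor beta (TGF-beta) genes. The secreted Wnt modulator Sfrp2 rose (1.70, SE 0.26, adjusted p = 0.0415) and Wnt4 fell (-1.15, SE 0.16, adjusted p = 0.0268) among 31 Wnt genes (3 higher and 2 lower adjusted over the list alone; 5 and 2 with the block). The list did not pass (median 0.27, camera adjusted p = 0.0653; 0.0248 without mandible library 3 and 0.0312 without tibia library 1), and the abundant antagonists Wif1 (0.67) and Sfrp4 (0.45) did not either. Bmp2, a growth factor of bone formation, rose (1.04, SE 0.15, adjusted p = 0.0385) among 32 genes of the joint BMP and TGF-beta list (5 higher adjusted over the list alone; 6 higher and 1 lower with the block), while Id3 (0.29) and Id2 (0.53) did not pass. That list passed at a median of 0.34 (camera adjusted p = 0.00276; 0.0503 without tibia library 3), a call lost at adjusted p = 0.367 with an estimated correlation. Immediate early and stress genes were above 0 for all 20 members without any passing, also adjusted over the list alone (median 0.55, camera adjusted p = 0.00505; adjusted p = 0.429 with an estimated correlation), and 7 were higher with the block. That list did not pass without mandible library 1, mandible library 2 or tibia library 3 (adjusted p = 0.0594, 0.0883 and 0.176), and its median was 0.31 and 0.35 without mandible library 2 or tibia library 3. Fos stood at 0.61 (adjusted p = 0.686; 0.0332 with the block) and Zfp36 at 0.91 (adjusted p = 0.449; 0.0105 with the block). Cell cycle genes had a median of -0.19 with none of 22 passing, also adjusted over the list alone (1 lower with the block; camera adjusted p = 0.000364; 0.101 without tibia library 3, at a median of 0.04; adjusted p = 0.432 with an estimated correlation). Pcna stood at 0.06 (-0.08 after quantile normalization) and Rrm2 at -0.56 (adjusted p = 0.873; 0.0311 with the block). The cell cycle median was -0.03 and -0.45 without mandible library 1 or 3 and -0.37 without tibia library 1, and Rrm2 was at -0.25 and -0.94 without mandible library 1 or 3 and at -0.20 without tibia library 3.

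Hedgehog genes (median 0.26, camera adjusted p = 0.0686; 0.0118 without dissection 3 and 0.000461 without mandible library 3) and fibroblast growth factor genes (0.25, adjusted p = 0.494) did not pass and had 0 passing members, also adjusted over the list alone (2 and 1 higher with the block). Their most abundant members were Boc (-0.23), Smo (0.29), Fgfr1 (0.41) and Dusp6 (0.13; -0.02 after quantile normalization). Hypoxia and glycolysis genes (0.05, mean 0.06, camera on the lower side, adjusted p = 0.486) and sex-linked genes (-0.07, mean 0.02, lower side, adjusted p = 0.530) did not pass either, again with 0 members adjusted over the list alone. Gapdh and Aldoa stood at 0.00 and 0.15 (-0.03 for Aldoa after quantile normalization), and Eif2s3y and Ddx3y at -0.05 and -0.10. Of the 30 lists, 10 passed higher and 7 lower in the mandible, and 3 and 1 with an estimated correlation: the jaw patterning, Dlx and Msx, and ameloblast lists higher and the Hox list lower. With both the block and an estimated correlation 0 lists passed, the lowest adjusted p being 0.221.

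**Figure D3:**
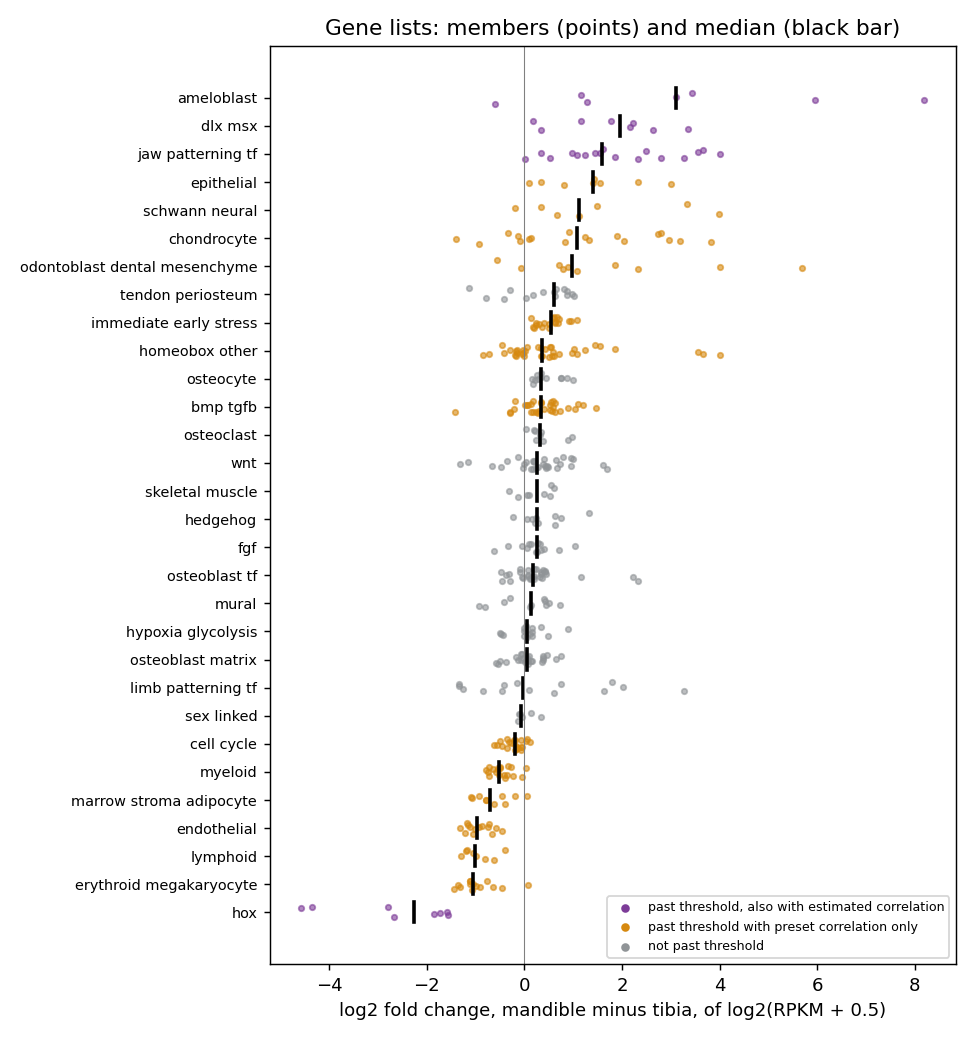
Log2 fold change, mandible minus tibia, of each tested member (points) and the median (black bar) of the 30 gene lists, in purple where camera passed also with an estimated correlation, in orange with the preset correlation only, and in grey where it did not pass. The ameloblast list lies highest, with a median of 3.11, and the Hox list lowest, at -2.26.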

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

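The settings without both libraries of dissection 3, with the transcript length trend removed (alone or with the block), with the block and quantile normalization, and with the highest transcript per gene were chosen after the data were seen. Of the 99 named genes 44 passed, and 0 of these changed sign under any setting run. Each of the 124 genes that passed had no overlap between its mandible and tibia values. Leaving out libraries, another pseudocount, library weights or the block could therefore not change a sign, and those settings are no support for the direction. For 0 of the 17 lists that passed did the direction of the test change, but the medians of the myeloid and cell cycle lists crossed 0 without tibia library 3, at 0.16 and 0.04. Changes of sign fell on 19 of the 55 named genes, and changes of test direction on 7 of the 13 lists, that had not passed. The cause was not tested except where fewer libraries or genes explain a lower count by construction. Read depth ran from 49.2 to 58.1 M reads, and what it limits was not tested. Simulated changes of 1 on the log2 scale were recovered in 4.4% of genes without the block, so that smaller changes were mostly out of reach.

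Against 111 genes higher and 13 lower, library weights gave 835 and 207, the block 566 and 262, leaving out dissection 3 gave 557 and 167, the block with length trend removed 361 and 420, and the block with quantile normalization 360 and 424. A filter at a mean RPKM of 2 gave 58 and 3, and removal of the length trend alone gave 70 higher. No filter gave 82 and 10, and kept 66 of the 124 calls. Leaving out libraries gave 32 to 822 higher and 5 to 346 lower, the top of each range being the block without dissection 3. Without mandible library 1, 2 or 3 the totals were 46, 40 and 141, and without tibia library 1, 2 or 3 they were 37, 48 and 72. Fewer libraries lower the power by construction, which cannot account for the 141, above the 124 of all libraries. Without dissection 1, 2 or 3 under the block they were 448, 198 and 1168.

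For transcription factors (17 higher, 8 lower), library weights gave 71 and 20, the block 50 and 23, leaving out dissection 3 gave 61 and 17, the block with length trend removed 40 and 29, the block with quantile normalization 38 and 27, and the filter at 2 gave 7 and 2. Leaving out libraries gave 9 to 77 higher and 4 to 21 lower. Adjusted over the list alone (26 higher, 10 lower), the same settings gave 85 and 25, 59 and 23, 79 and 18, 42 and 33, 42 and 31, and 7 and 2, and no filter gave 19 lower. Leaving out libraries gave 13 to 85 higher and 6 to 22 lower. Lists that passed (10 higher, 7 lower) fell to 3 and 1 with an estimated correlation and to 0 and 0 when the block was added to it, and fry gave 2 lower. With the libraries complete or without dissection 3, and the correlation not estimated, lists that had not passed did so under 9 settings for Wnt, 7 for hedgehog, 5 for osteocyte and 1 each for fibroblast growth factor and osteoblast factors. The 7 lists that lost a call there lost it under fry alone. Factors detected at one site (22 mandible, 7 tibia) came to 73 and 26 by the group mean, 47 and 15 without dissection 3, and 12 for the tibia at an RPKM of 0.5. Leaving out single libraries gave 22 to 43 and 7 to 12, the highest without mandible library 3. Of the 44 named genes that passed, 20, 20 and 9 no longer did without mandible library 1, 2 or 3, and 21, 18 and 11 without tibia library 1, 2 or 3. With all libraries, no filter ended 16 of the 44 calls. Quantile normalization and removal of the length trend ended 6 each, the highest transcript 5 and median-of-ratios scaling 4. The block ended 0 of the 44 calls and added 15 among the other named genes, each given with its value beside the result, and changed no other call among named genes. Alternatives meant for counts were not run, because the values are RPKM.

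Sign changes among genes that had not passed were as follows. With quantile normalization, with or without the block, log2 fold changes were -0.01 for Ctsk, -0.08 for Pcna, -0.03 for Aldoa, -0.02 for Dusp6 and -0.05 for Runx2. Median-of-ratios scaling gave -0.06 for Bglap, -0.08 for Pcna, 0.00 for Dusp6 and -0.05 for Runx2. With the length trend removed, with or without the block, Bglap was at -0.04, Pcna at -0.09 and Runx2 at -0.04. Library weights gave 0.11 for Tgif1 and 0.01 for Gapdh, and leaving out dissection 3 gave 0.14 and 0.02. Ranges over left-out libraries and dissections were -0.21 to 0.14 for Tgif1, -0.25 to 0.56 for Bglap, -0.38 to 1.92 for Tnnc2, -0.22 to 1.52 for Acta1, -0.15 to 0.32 for Pcna, -0.03 to 0.28 for Aldoa, -0.91 to 0.40 for Boc, -0.34 to 1.40 for Fmod, -1.71 to 0.64 for S100a8, -1.62 to 0.45 for Ngp, -1.20 to 0.46 for Cd74, -0.27 to 0.28 for Gapdh, -0.43 to 0.34 for Eif2s3y, -0.27 to 0.01 for Ddx3y, -0.33 to 0.67 for Sp7 and -0.09 to 0.73 for Sfn. Without a sign change on leaving out libraries, values that moved by over 1.5 times ranged from -0.61 to -0.16 for Prrx1, -0.65 to -0.04 for Creb3l1, 0.09 to 0.32 for Ctsk, 0.21 to 0.48 for Acp5, 0.34 to 0.88 for Wif1, 0.30 to 0.69 for Sfrp4, 0.18 to 0.43 for Id3, 0.32 to 0.75 for Id2, 0.00 to 0.31 for Dusp6, 0.05 to 0.11 for Runx2, -1.17 to -0.41 for Egfl7, -1.41 to -0.60 for Esam, -1.18 to -0.19 for Rgs5 and 0.38 to 1.36 for Acta2, besides those given with their results.

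For lists the direction is that of camera or fry, which can differ from the sign of the median given here. The skeletal muscle list turned to the higher side at medians of 0.39 (pseudocount 0.1), 0.03 (no filter), 0.13 (quantile normalization, with or without the block), 0.16 (median-of-ratios), 0.29 (library weights), 0.26 (block, block with estimated correlation, fry, and without dissection 3), 0.12 (length trend removed, with or without the block) and 0.47 (highest transcript). The limb list turned at 0.02 (no filter), -0.18 (quantile), -0.12 (median-of-ratios), -0.16 (length trend removed) and -0.02 (fry). The mural list turned at 0.50 (library weights), 0.54 (without dissection 3) and 0.14 (fry), and the osteoblast matrix list at -0.08 (quantile) and 0.05 (fry). Fry also turned the hypoxia list at 0.05 and the sex-linked list at -0.07. Medians over left-out libraries were -0.35 to 0.32 for limb, -0.23 to 0.58 for mural, 0.09 to 0.80 for tendon and periosteum, -0.33 to 0.67 for skeletal muscle, -0.26 to 0.18 for sex-linked, -0.14 to 0.21 for hypoxia, 0.23 to 0.51 for hedgehog, 0.10 to 0.18 for osteoblast factor, 0.00 to 0.29 for osteoblast matrix, 0.13 to 0.48 for osteocyte, -1.11 to 0.16 for myeloid and -0.45 to 0.04 for cell cycle genes.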

Other observations

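The tests below on cell types, dissection 3 and the direction of calls were chosen after those results were seen, while the split counts and the retinoid test were set out before their outcome. The genes of this paragraph and the next were picked after their values were seen, and as picked genes they stand for no group. Crabp1, a retinoic acid binding protein, was at 65.2 ± 7.53 RPKM in the mandible against 12.0 ± 1.14 in the tibia (2.40, SE 0.19, adjusted p = 0.00337). The retinal dehydrogenase Aldh1a3 (2.29, adjusted p = 0.0278), the retinol dehydrogenase Rdh10 (1.29, adjusted p = 0.0304) and the aldehyde oxidase Aox3 (2.57, adjusted p = 0.00819) rose in the mandible, while the receptor gene Rarb did not pass, at 1.73 (adjusted p = 0.104; 0.00201 with the block). Tac1, which encodes the precursor of substance P, rose by 3.35 (SE 0.53, adjusted p = 0.0472) and Nts, encoding neurotensin, by 2.48 (SE 0.26, adjusted p = 0.00979). Dio3, which inactivates thyroid hormone, and its neighbour Dio3os rose by 3.19 and 2.32 (adjusted p = 0.0241 and 0.00269), and the Wnt and BMP antagonist Sostdc1 rose by 2.78 (adjusted p = 0.00303).

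The noncoding transcripts Dlx4os (2.74, adjusted p = 0.00240), Msx1os (2.22, adjusted p = 0.0107), Dlx1as (2.02, adjusted p = 0.0290) and Dlx6os1 (1.70, adjusted p = 0.0271) rose in the mandible. Of the homeobox genes they are named for, Dlx4 and Msx1 rose, while Dlx6 at 0.18 (adjusted p = 0.965) and Dlx1 at 2.16 (adjusted p = 0.0661; 0.0114 with the block) did not pass. Reads of each pair cannot be told apart where the transcripts overlap, because the strand setting of the counting is not known.

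A hypothesis that the whole retinoic acid pathway is higher in the mandible was tested on the 17 tested members of a pathway list that had not been looked at, leaving out the 5 genes above. Their median log2 fold change was 0.07 against 0.12 for all genes (camera p = 0.743, and 0.842 with an estimated correlation), with 12 above 0 and 0 passing. This argues against a shift shared by these 17 members and leaves the single genes as they are. The 5 genes left out were picked after their values were seen, so nothing follows for the pathway as a whole. With the block 1 of the 17, Crabp2, was higher (0.74, adjusted p = 0.0240).

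The ameloblast, odontoblast, cartilage, Schwann cell and epithelial lists were on the higher side in the mandible, of which the ameloblast list alone kept its call with an estimated correlation (adjusted p = 0.0325, against 0.0691, 0.367, 0.111 and 0.0691). A lower share of osteoblasts in the mandible sort, with the same mix of other cells at both sites, would raise markers of all other types. The endothelial median of -0.97, with 14 of 14 genes below 0, argues against that form of it. If the mix of other cells differs between the sites, endothelial genes cannot decide, and a lower share stays open. Cells of these types among the sorted cells and expression by the mandible osteoblasts themselves cannot be told apart in pooled cells: the lowest share of members above 0, 72.2% for cartilage, follows from lists picked for being higher, and the 60% of osteoblast matrix genes above 0 bears on neither. Genes differed within lists, with Amelx at 1005 RPKM against 2.29 in the tibia but Klk4 at 0.727 against 1.60, and Col2a1 at 86.2 against 12.6 but Acan at 7.70 against 7.36, and 5 of 7 ameloblast, 3 of 10 odontoblast, 12 of 18 cartilage, 5 of 7 Schwann and 1 of 8 epithelial genes had a mean RPKM of at least 1 in the tibia. The fluorescence gate should remove cells without Col1a1 promoter activity, though not odontoblasts, which are known to use it, and 5 of the 10 odontoblast and 1 of the 7 ameloblast genes stand in another list too.

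Dissection 3 stood apart from the others at both sites. Across 12625 genes its difference from dissections 1 and 2 fell with transcript length (Spearman's rho -0.40 in the mandible and -0.25 in the tibia, over genes, which are not independent), as a loss of long transcripts predicts. In the shortest of 4 equal length classes (median 1.23 kb) the median difference was 0.56 in the mandible and 0.49 in the tibia, and in the longest (5.54 kb) it was -0.19 and 0.01. More blood and marrow cells in dissection 3 may add to it, since the lowest of the erythroid and myeloid medians was still 1.13 above the other dissections after the length trend was removed. Both stay open, and no further explanation was tested, because the design gives none for a dissection.

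More genes were called higher than lower in the mandible. A scaling difference between the sites predicts an even split after quantile normalization. Without the block 85.3% of the calls were still higher, which argues against scaling as the whole cause for those genes. With the block the share came to 45.9%, but quantile normalization takes out a scaling difference and a broad real change alike, so for those calls both stay open.

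With 3 libraries against 3 there are 10 splits, too few for a share under 0.05. The real split gave 124 genes and 25 transcription factors, and the highest of the others gave 0 and 0. Every other split mixes both sites in each group, which puts the site difference into its spread. Its 0 gene calls therefore do not count as support. For lists the real split gave 17 and the highest other 16, and for each of the 3 counts 1 split, the real one, reached its value. The split with 16 lists set mandible libraries 1 and 2 with tibia library 3 against the rest and, like the real one, parted all 3 pairs. The 2 further splits that part all pairs gave 7 and 6 lists and 0 genes each.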
